A study of Mus musculus with 15 samples.

How the data were processed

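RNA from whole kidney of 15 mice was measured, 5 each of wild type (WT), Hyp and cFGF23-Hyp. Groups follow the sample titles and the design text of 5 mice per group. WT and Hyp mice received PBS and cFGF23-Hyp mice an adeno-associated virus (AAV) encoding cFGF23, per the labels. Libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols, and whether strand was kept is not stated. The aligner, the counting tool, the annotation and the authors' test are not given in the sources used here. The submitters' processing notes name the build mm10, yet only 538 of 25727 genes (2.09%) start at the same position as in the GRCm38 annotation, so coordinates are printed as the deposited tables give them and were not combined with any other annotation.

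The authors deposited 2 tables, Hyp against WT and cFGF23-Hyp against Hyp, each with raw read counts per gene and library. A second set of deposited columns holds a normalized signal, and each of these columns equalled the counts times 1 constant per library. The 20 deposited FPKM columns of per-sample values were not used. Each table also gives the authors' log2 fold change, p-value and adjusted p per gene, which the authors computed themselves, and these serve only as the authors' own values.

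The tables list 28216 and 28110 genes. Counts of the Hyp libraries were identical in both, and 27122 genes stood in both, so the tables were joined. Genes in only 1 table (1094 and 988, with total counts of at most 11 and 32) were left out. Entries without a gene name (299, holding 0.219% to 0.363% of the counts of a library) stayed out of library sizes and tests, which left 26823 genes. Total counts per library ran from 13083190 to 21829906. Reads carry no molecular identifiers, so errors over mice include counting error, and no interval for single libraries is given. Within a group, the lowest chi-square per degree of freedom between a pair of libraries was 8.98, so no library was a copy of another within sampling noise. The labels describe mice, 1 library each, and give no batch, cage or date.

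Differential expression was tested on the raw counts with edgeR 4.0.16 (quasi-likelihood F test, glmQLFit with default settings) under R 4.3.3, with TMM scaling and the filterByExpr filter, which kept 15789 genes. All 15 libraries entered 1 fit with a mean per group and no covariate. The 3 comparisons were Hyp against WT, cFGF23-Hyp against Hyp and cFGF23-Hyp against WT, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors are the log2 fold change divided by the square root of F. CPM values use the TMM-scaled library size, and log2 CPM a prior count of 2. All adjusted p-values of genes come from this test unless another tool is named. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run as alternatives.

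Gene lists for pathways, nephron segments, other cell types and neighbouring tissues (43 lists, 975 entries, of which 962 matched by symbol, 4 by synonym and 9 not at all) were fixed beforehand. The 39 lists with at least 5 tested genes were tested with camera (preset correlation 0.01), adjusted over the 39 lists within a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction and does not compare the list with other genes, were run beside it. A list score of a library is the mean over members of log2 CPM minus the mean of the gene over the 15 libraries. Scores were compared by exact two-sided permutation tests, chosen after the data were seen.

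Named genes follow a rule fixed before the data were examined. It takes Phex, then per comparison the up to 8 protein-coding genes with the largest rise and the 8 with the largest fall among called genes with a mean log2 CPM of at least 1. It adds up to 4 members with the smallest adjusted p of each called list and up to 2 of each other list, and a fixed set of genes for phosphate and vitamin D handling, FGF signalling, injury, inflammation and fibrosis. Some genes that the rule names are not reported here. Synpr was singled out after its values were seen.

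Alternatives fixed before the data were examined were DESeq2's size factors, DESeq2, limma-voom, no filter, a filter of at least 1 CPM in at least 5 libraries, fits of only the 2 groups compared, the replicate number as a block, the library labelled WT_5 placed in Hyp as its genotype label says, and each library left out in turn. Added after the data were seen were fits without WT_5 and cFGF23-Hyp_5, fits without these and cFGF23-Hyp_3, and the removal of the trend with gene length. For an uncalled gene, 36 turns of sign by less than 1 standard error were counted as no change. Replicate numbers were not taken to pair mice across groups, since the labels do not say that they do. A structure by number is not excluded, as 6 of 15 same-numbered pairs had a correlation of deviations above 0.1. The shared Hyp libraries were handled by 20 simulations of unchanged groups and by the 10 ways to split them 3 and 2. For each comparison, 100 of the 126 splits of its 10 libraries into 5 and 5 were refitted, the real one included.

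The tests were tried on simulated counts with known changes. For Hyp against WT (15645 simulated genes), edgeR recovered 49.3%, 70.1% and 92.4% of genes changed 1.5-, 2- and 4-fold and called 10 unchanged genes. For cFGF23-Hyp against Hyp (15635 genes) the shares were 41.8%, 71.6% and 92.4%, with 7 unchanged genes called, and for cFGF23-Hyp against WT 47.8%, 71.6% and 92.4%, with 4. Of the 39 unchanged lists, camera with the preset correlation called 0, 3 and 1 in the 3 comparisons. Each gene was drawn on its own there, so members of a list were not correlated and these counts cannot test the preset correlation. In the data the estimated correlation was 0.819 for oxidative phosphorylation genes in Hyp against WT.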

Results

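Gene expression was measured by RNA sequencing of whole kidney from 15 mice at 4 months of age. Hyp mice lack working Phex, an endopeptidase encoded on the X chromosome, and have high levels of FGF23, the bone hormone that lowers phosphate reabsorption in the kidney. cFGF23 is the carboxy-terminal part of FGF23, which can compete with the intact hormone for its receptor complex. There were 3 groups of 5 mice: WT given PBS, Hyp given PBS, and Hyp given an AAV vector encoding cFGF23 (cFGF23-Hyp). The vector was given intravenously at 4 weeks of age (1e12 vector genomes per mouse), 3 months before death. The deposited raw counts per library ran from 13083190 (cFGF23-Hyp_3) to 21829906 (WT_4), and 15789 genes were tested.

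Phex, the gene disrupted in Hyp mice (ENSMUSG00000057457, chromosome X, 155945071 to 156198308 as the deposited tables give it), had 0 to 3 counts in every library, WT included. The kidney level of Phex therefore could not check the genotype labels. Xist was at most 0.622 CPM and the Y-linked Ddx3y 52.5 to 75.4 CPM in the 15 libraries. Fgf23 was not analysed here.

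Of the 15 libraries, 3 lay apart from their groups. The library labelled WT_5 is WT by its title, while its genotype label names a Phex knockout and its cell type label Hyp. Its score for type I interferon genes (mean log2 difference from the average library) was 1.12, against -0.90 to -0.57 in WT_1 to WT_4. The library labelled cFGF23-Hyp_5 had a score of -0.84, against 0.35 to 2.04 in the other 4 cFGF23-Hyp libraries. Synpr, a synaptic vesicle gene singled out after its values were seen, was at 21.8 to 40.6 CPM in WT_1 to WT_4 and 42 CPM in cFGF23-Hyp_5. In WT_5 it was at 0.542 CPM, in the range of the Hyp libraries (0.303 to 1.29 CPM). Synpr values of cFGF23-Hyp_1 to cFGF23-Hyp_4 are not given here, so those printed do not tell an untreated Hyp mouse from a treated one. Both libraries were kept in the groups their titles give, and counts without them are printed beside the main ones. The library furthest from the rest was cFGF23-Hyp_3, at -50.60 on the first principal component, where the other 14 lay at -8.16 to 15.79. Its chi-square per degree of freedom was 55.29 to 75.48 with the other libraries, against at most 46.57 for pairs without it. It also had the fewest detected genes (20444) and the lowest mitochondrial share (6.635%), and leaving it out alone took the calls in Hyp against WT from 54 to 345.

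The comparison of Hyp with WT asks how the kidney transcriptome differs when Phex is lost. In Hyp kidneys, 28 genes rose and 26 fell, 22 of them by more than 2-fold. Most of these genes lost their call, though none its sign, with any 1 of WT_1 to WT_4 or of the Hyp libraries left out (7 to 15 calls). The largest rise was in the carboxylesterase gene Ces1g, from 3.11 ± 3.64 CPM in WT to 121 ± 7.65 CPM in Hyp (SD, n = 5 each). Etv4 and Etv5, transcription factor genes induced by FGF receptor signalling, rose by 1.61 ± 0.27 and 0.82 ± 0.16 on the log2 scale (estimate ± SE, adjusted p = 0.022 and 0.042, edgeR quasi-likelihood test). Dnase1, which encodes a secreted endonuclease, fell from 1780 ± 356 to 585 ± 67.7 CPM (SD, n = 5 each).

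**Figure D1:**
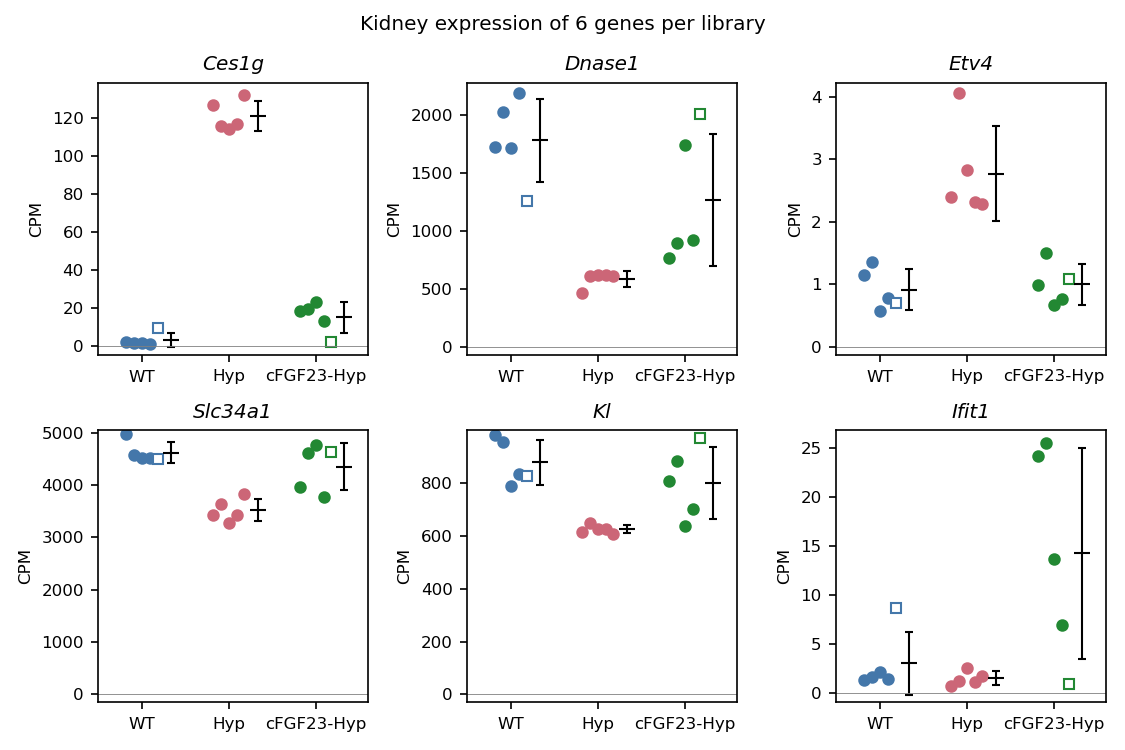
Expression in CPM (vertical axis) of 6 genes in each of the 15 libraries by group, with the group mean and SD (n = 5) in black. Open squares mark WT_5 and cFGF23-Hyp_5. Ces1g lay at 114 to 132 CPM in the Hyp libraries and at most at 22.9 CPM in the others, and Ifit1 at 6.91 to 25.5 CPM in cFGF23-Hyp_1 to cFGF23-Hyp_4 but at 0.927 CPM in cFGF23-Hyp_5.

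Ces1g (ENSMUSG00000057074, chromosome 8, 94028997 to 94063936) rose by 5.27 ± 0.58 on the log2 scale (SE, adjusted p = 0.0013). Its WT mean includes 9.59 CPM in WT_5, against 1.07 to 2.01 CPM in WT_1 to WT_4. Without WT_5 and cFGF23-Hyp_5, left out after the data were seen, the rise was 6.37 ± 0.19 (adjusted p = 7.0e-11). As WT_5 was the extreme WT library for Ces1g, the smaller error follows partly from that choice. DESeq2 gave Ces1g no adjusted p, and the authors' deposited table lists 1.000. The other large rises were in Jchain, the joining chain of secreted IgA and IgM (1.87 ± 0.38, adjusted p = 0.048), Greb1 (1.60 ± 0.29, adjusted p = 0.033) and Tmem252 (1.58 ± 0.30, adjusted p = 0.035). Nat8f2 (chromosome 6, 85842404 to 85846140) rose from 35.8 ± 10.4 to 98.3 ± 8.85 CPM and the growth factor gene Fgf10 (chromosome 13, 118806327 to 118928651) from 2.71 ± 0.957 to 7.02 ± 1.05 CPM (SD, n = 5 each). Slc22a8, the basolateral organic anion transporter of the proximal tubule, rose by 1.16 ± 0.22 (adjusted p = 0.034), and Npl, an enzyme of sialic acid breakdown, by 1.02 ± 0.21 (adjusted p = 0.049). The largest falls after Dnase1 (chromosome 16, 3854806 to 3857888; -1.61 ± 0.24, adjusted p = 0.0097) were in Prkag3, a regulatory subunit of AMP-activated kinase (-1.45 ± 0.22, adjusted p = 0.014), and the cadherin gene Fat2 (-1.45 ± 0.25, adjusted p = 0.022). Ftcd, an enzyme of histidine breakdown, fell by 1.44 on the log2 scale (SE 0.21, adjusted p = 0.0097). Ctnna2, Ces2b and Susd2 had log2 changes of -1.31, -1.23 and -0.98, with adjusted p of 0.031, 0.049 and 0.0055. Itgb6, an epithelial integrin subunit, fell from 129 ± 27.6 to 64.4 ± 16.3 CPM (SD, n = 5 each; adjusted p = 0.048). Ces1g, Ces2b, Nat8f2 and the immunoglobulin genes have close paralogs, so their counts are uncertain where reads fit more than 1 copy.

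No gene of phosphate and vitamin D handling passed edgeR's test with all 15 libraries in this comparison, while Kl and Slc34a1 fell by other tools and without WT_5 and cFGF23-Hyp_5. Kl, the co-receptor of FGF23, was at 877 ± 85.4 CPM in WT and 625 ± 15.8 in Hyp (SD, n = 5 each), a log2 change of -0.49 ± 0.10 (SE, adjusted p = 0.055). Slc34a1, the main phosphate transporter of the proximal tubule, was at 4620 ± 198 CPM in WT and 3524 ± 214 in Hyp (adjusted p = 0.059). Without WT_5 and cFGF23-Hyp_5 the adjusted p was 0.022 for Kl and 0.046 for Slc34a1, with DESeq2 0.0014 and 1.3e-04, and with limma-voom 0.049 and 0.046. Cyp24a1, which degrades active vitamin D, had a log2 change of 1.69 ± 0.59 (adjusted p = 0.228), Cyp27b1, which makes it, 0.86 ± 0.45 (adjusted p = 0.418), and Slc34a3 -0.06 ± 0.16 (adjusted p = 0.893). Over the 22 tested genes of this list, 2 rose and 3 fell when adjusted over the list alone, 0 over all genes tested, and camera gave an adjusted p of 0.053. The FGF receptor genes Fgfr4 and Fgfr1 had log2 changes of -0.26 ± 0.06 and 0.05 ± 0.09 (adjusted p = 0.085 and 0.856).

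Inflammatory genes, which the series title names, lay higher as groups. Of 30 genes of the NF-kB and cytokine list, 27 had a positive log2 change (median 0.29; camera adjusted p = 1.1e-06, but adjusted p = 0.306 with an estimated correlation). In that list 5 genes rose when adjusted over the list alone and 0 over all genes tested. Lcn2, a secreted marker of tubular injury, was at 1.29 ± 0.0698 CPM in WT and 2.77 ± 0.937 in Hyp (SD, n = 5 each; adjusted p = 0.070). Cxcl16, Relb and Icam1 had log2 changes of 0.60, 0.53 and 0.36, with adjusted p of 0.117, 0.130 and 0.192. B and plasma cell genes had a median of 1.31 over 11 genes, with 6 risen when adjusted over the list alone and 1, Jchain, over all genes (camera adjusted p = 3.2e-06, adjusted p = 0.306 with an estimated correlation). Igha was at 51.1 ± 24.9 CPM in WT and 186 ± 71 in Hyp (SD, n = 5 each; adjusted p = 0.068). Macrophage markers had a median of 0.43, with 20 of 21 genes positive and 2 risen when adjusted over the list alone (camera adjusted p = 5.4e-06, adjusted p = 0.342 with an estimated correlation). Complement genes had a median of 0.36 over 22 genes (adjusted p = 0.0084, and adjusted p = 0.430 with an estimated correlation), and MHC class II genes 0.23 over 12 (adjusted p = 0.036, and adjusted p = 0.496 with an estimated correlation). With 1 library left out, the MHC class II call was lost without WT_1, WT_2, Hyp_3 or Hyp_5 (medians 0.16, 0.16, 0.21 and 0.16, adjusted p = 0.132, 0.079, 0.063 and 0.065), and the B and plasma cell median was 0.75 without Hyp_4. The medians of T and NK cell (0.29) and type I interferon genes (-0.52) did not pass camera (adjusted p = 0.195 and 0.065). The direction of the interferon median turned without WT_5 and cFGF23-Hyp_5, to 0.14 with 23 of 33 genes positive, against 4 of 33 with all libraries (adjusted p = 0.190). Tnf, Il6 and Ccl2 were under the count filter, at no more than 0.35, 0.0614 and 0.829 CPM in any library.

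Matrix and vessel genes also lay higher. Of 42 fibrosis and matrix genes, 38 were positive (median 0.31; camera adjusted p = 2.0e-08, adjusted p = 0.342 with an estimated correlation), though 0 rose when adjusted over the list alone. Col6a1, Col5a1 and Col14a1 had log2 changes of 0.74, 0.68 and 0.53 (adjusted p = 0.133, 0.184 and 0.208), Col1a1 0.32 (adjusted p = 0.554) and Tgfb1 0.22 (adjusted p = 0.627). All 22 endothelial markers were positive in the fit of all libraries, with a median of 0.33 and 4 risen when adjusted over the list alone (adjusted p = 4.2e-08, and adjusted p = 0.342 with an estimated correlation). Podocyte markers had a median of 0.23, with 4 of 18 risen when adjusted over the list alone (adjusted p = 1.9e-04, and adjusted p = 0.306 with an estimated correlation). Podxl had a log2 change of 0.43 ± 0.10 (adjusted p = 0.069). Smooth muscle, pericyte and renin cell markers had a median of 0.11 (adjusted p = 0.018, and adjusted p = 0.430 with an estimated correlation), with Lmod1 risen by 0.70 ± 0.14 (adjusted p = 0.048). That median was 0.07 without WT_2, Hyp_2 or Hyp_5, 0.17 without WT_3 or Hyp_3, 0.19 without Hyp_1 and 0.21 without WT_4. The call was lost without Hyp_5 (adjusted p = 0.074) or WT_5 (median 0.14, adjusted p = 0.066). The FGF receptor and ERK feedback list had a median of 0.30, with Etv4 and Etv5 risen over all genes and 3 of 26 when adjusted over the list alone (adjusted p = 1.7e-04, and adjusted p = 0.342 with an estimated correlation). Without WT_1 its median was 0.17. Egr1, an immediate target of this pathway, varied widely between mice (50.2 ± 51 CPM in WT and 31.1 ± 32.3 in Hyp, SD, n = 5 each; adjusted p = 0.743).

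Lists for tubular injury (median 0.13) and hepatocyte genes (0.50) passed camera upward with adjusted p of 0.033 and 0.012, and had adjusted p of 0.496 and 0.342 with an estimated correlation. The injury call was lost without WT_1 (median 0.07), WT_2 (0.10), Hyp_4 (0.10), Hyp_5 (0.02) or cFGF23-Hyp_1 (0.12), with adjusted p of 0.305, 0.082, 0.056, 0.217 and 0.051, and its median was 0.20 without WT_3 and 0.19 without Hyp_2. The hepatocyte median, over 5 or 6 genes, was 0.02 without Hyp_5 and 0.82 to 1.13 without any other single library except Hyp_2 or Hyp_4. Havcr1, Vcam1 and Spp1 had log2 changes of -0.04, 0.24 and 0.24 (adjusted p = 0.962, 0.561 and 0.413). Ttr, the transthyretin gene in the hepatocyte list, had a log2 change of 3.07 ± 0.70 (adjusted p = 0.070), and Alb 1.45 ± 0.43 (adjusted p = 0.155). Without WT_5, where Ttr was at 463 CPM, and cFGF23-Hyp_5, Ttr rose by 4.22 ± 0.27 (adjusted p = 1.0e-06). WT_5 had the highest Ttr of the WT libraries and was left out after the data were seen. The smaller error of Ttr thus follows partly from that choice. Among lists that lay lower, oxidative phosphorylation had a median of -0.22 with 0 of 66 genes positive (camera adjusted p = 1.1e-09, adjusted p = 0.496 with an estimated correlation). The heat shock list had a median of -0.52, with 4 of 15 genes fallen when adjusted over the list alone (adjusted p = 2.2e-07, and adjusted p = 0.342 with an estimated correlation). Hsp90aa1 and Hspd1 had log2 changes of -0.73 and -0.46 (adjusted p = 0.179 and 0.133). Androgen-dependent genes had a median of -0.48 (adjusted p = 0.0015, and adjusted p = 0.370 with an estimated correlation), with Hsd17b11 fallen (-0.86 ± 0.18, adjusted p = 0.049). Unfolded protein response, ribosomal protein, fatty acid oxidation and gluconeogenesis lists had medians of -0.21, -0.09, -0.13 and -0.11, with camera adjusted p of 0.0051, 0.0084, 0.029 and 0.033. Their adjusted p with an estimated correlation was 0.496, 0.788, 0.496 and 0.370. Without WT_4 the first 3 lost their call (medians -0.10, -0.05 and -0.08, adjusted p = 0.146, 0.107 and 0.111). The fatty acid call was also lost without WT_2, WT_3, Hyp_1, Hyp_2 or cFGF23-Hyp_4 (medians -0.13 to -0.10, adjusted p = 0.050 to 0.093). That of gluconeogenesis genes was lost without WT_5, Hyp_3 or Hyp_4 (medians -0.12, -0.09 and -0.09, adjusted p = 0.054, 0.137 and 0.066), and their median was -0.06 without WT_1. Slc13a1, a sulphate transporter, rose by 0.72 ± 0.13 (adjusted p = 0.031), while the proximal tubule list as a whole had a median of -0.14 (adjusted p = 0.195).

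In total camera called 19 of 39 lists, 12 higher and 7 lower, none with an estimated correlation, and fry called 3 (NF-kB, B and plasma cell, and podocyte). Without WT_5 and cFGF23-Hyp_5, 228 genes were called (112 higher), all 54 among them. Lcn2, Cxcl16, Igha, Col5a1, Hsp90aa1 and Hspd1 passed in that fit (adjusted p = 0.043, 0.025, 0.032, 0.040, 0.042 and 0.028). Interferon gamma and MHC class I genes and mitochondrially encoded genes gained a call there (medians 0.33 and -0.18, camera adjusted p = 0.0015 and 0.045, adjusted p = 0.496 for each with an estimated correlation). In the same fit smooth muscle and gluconeogenesis genes lost theirs (medians 0.11 to 0.14 and -0.11 to -0.12, adjusted p = 0.092 and 0.053). The hepatocyte median there was 0.91, from 0.50. DESeq2 called 356, limma-voom 76 and edgeR on the 2 groups alone 516. Leaving out any 1 of WT_1 to WT_4 or of the Hyp libraries left 7 to 15 calls, while leaving out WT_5, cFGF23-Hyp_3, cFGF23-Hyp_4 or cFGF23-Hyp_5 gave 160, 345, 96 or 109. The authors' deposited table lists 1336 genes at an adjusted p below 0.05 (578 higher, 758 lower), and 50 of the 54 are among them with the same sign.

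Over all genes tested, log2 changes of Hyp against WT were higher in longer genes (Spearman's rho = 0.21, genes not being independent). With this trend taken out of the signed test statistics, cameraPR called 21 lists, 18 of the 19 among them. Oxidative phosphorylation, matrix and endothelial genes kept their call (adjusted p = 2.4e-07, 1.0e-06 and 2.4e-07, but 0.496, 0.342 and 0.342 with an estimated correlation and the trend left in). Ribosomal protein genes, with a median of -0.09, lost theirs (adjusted p = 0.081), and no median is given after the removal, which acts on test statistics. Calls were gained by phosphate and vitamin D, type I interferon and clock genes, all downward (adjusted p = 0.013, 0.0068 and 0.0092, but 0.370, 0.840 and 0.409 with an estimated correlation and the trend left in). The interferon median, -0.52 with all libraries, was 0.14 with 23 of 33 genes positive without WT_5 and cFGF23-Hyp_5, and it did not pass camera in that fit (adjusted p = 0.190). In cFGF23-Hyp against Hyp rho was -0.21, and 19 lists were called without the trend, the 14 included. Gained there were macrophage, tubular injury, thick ascending limb, principal cell and red blood cell genes, all downward (adjusted p = 0.045, 0.019, 0.035, 0.040 and 0.045, but 0.632, 0.632, 0.604, 0.604 and 0.632 with an estimated correlation and the trend left in). With WT_5 and cFGF23-Hyp_5 left out, the latter having a principal cell score of -0.37, their medians went from -0.19, -0.09, -0.11, -0.09 and -0.29 to -0.06, -0.06, -0.04, -0.01 and -0.19. None passed camera in that fit (adjusted p = 0.925, 0.574, 0.503, 0.460 and 0.235). In cFGF23-Hyp against WT rho was 0.00, and 8 of 9 lists kept their call, while the androgen-dependent list (median -0.22) lost it (adjusted p = 0.060).

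The comparison of cFGF23-Hyp with Hyp asks how treated and untreated kidneys of Phex-deficient mice differ. Interferon-stimulated genes stood highest. All 33 tested type I interferon genes had positive estimates in the fit of all libraries, with a median log2 change of 1.80, and 29 rose when adjusted over the list alone but 0 over all genes tested. Camera gave an adjusted p of 6.4e-35, and an adjusted p = 0.331 with an estimated correlation. Oas1a, an antiviral RNA sensor, was at 1.27 ± 0.264 CPM in Hyp and 15.8 ± 11.3 in cFGF23-Hyp (SD, n = 5 each; log2 change 3.65 ± 0.73 SE, adjusted p = 0.186). Oas2, Usp18 and Ifit1 had log2 changes of 3.44, 3.35 and 3.27, each with an adjusted p of 0.192.

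The treated libraries differed widely in these genes. The type I interferon score was 2.04, 1.79, 1.53 and 0.35 in cFGF23-Hyp_1 to cFGF23-Hyp_4 and -0.84 in cFGF23-Hyp_5, against -0.85 to -0.50 in the Hyp libraries. Its group means were 0.97 and -0.59, and an exact two-sided permutation test over 5 and 5 libraries gave p = 0.040 (adjusted over 39 lists p = 0.258), with 4 of 5 treated libraries above every Hyp library. WT_5 and cFGF23-Hyp_5 were set apart partly by this score, so interferon values without them rest on that choice and are no independent evidence of a rise. Without both, 27 of the 33 genes rose over all genes tested (median 2.04; camera adjusted p = 2.6e-135, adjusted p = 0.0032 with an estimated correlation, against 0.331 with all libraries). In that fit Oas1a rose by 3.93 ± 0.40 (adjusted p = 4.3e-04) and Usp18 by 3.63 ± 0.43 (adjusted p = 7.0e-04).

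Interferon gamma and MHC class I genes had a median of 0.44, with 22 of 24 positive and 6 risen when adjusted over the list alone (camera adjusted p = 1.3e-08, adjusted p = 0.331 with an estimated correlation). The GTPase genes Gbp3, Igtp and Irgm1 had log2 changes of 1.76, 1.57 and 1.56 (adjusted p = 0.231, 0.216 and 0.216). Without the 2 libraries, and with the same limit, the list was called with an estimated correlation (adjusted p = 0.044, against 0.331 with all libraries), and Gbp3 rose by 2.01 ± 0.24 (adjusted p = 7.2e-04).

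Several groups that lay higher in Hyp than in WT lay lower in cFGF23-Hyp than in Hyp. Both comparisons use the same Hyp libraries, which by itself favours opposite signs. Lists were not tested with these libraries split or simulated, so the falls alone are no evidence of a return towards WT. Medians were -0.29 for endothelial markers, -0.25 for matrix genes, -0.24 for the NF-kB and cytokine list, -0.20 for podocyte markers and -0.20 for smooth muscle markers. Their camera adjusted p was 8.0e-09, 2.5e-08, 4.7e-05, 0.0098 and 8.4e-04, and each had an adjusted p = 0.331 with an estimated correlation. Without cFGF23-Hyp_5, alone or together with WT_5, the endothelial and matrix medians were -0.19 and -0.16. Without Hyp_5 the NF-kB and smooth muscle medians were -0.10 and -0.12. The podocyte call was lost without Hyp_5 (median -0.17, adjusted p = 0.057) or cFGF23-Hyp_3 (-0.14, adjusted p = 0.068). B and plasma cell genes had a median of -0.51, with 5 of 11 fallen when adjusted over the list alone (adjusted p = 1.7e-05, and adjusted p = 0.331 with an estimated correlation), and of -1.23 without cFGF23-Hyp_3. In that list Ighg2b had a log2 change of -1.74 ± 0.43 (adjusted p = 0.216) and Jchain of -1.19 ± 0.37 (adjusted p = 0.291). Hepatocyte genes had a median of -0.71 (adjusted p = 0.034, and adjusted p = 0.331 with an estimated correlation) but no call without WT_5 and cFGF23-Hyp_5 (median -0.55 over 6 genes instead of 5, mean -0.91 from -0.66, adjusted p = 0.083). Their call was also lost without Hyp_2, Hyp_5 or cFGF23-Hyp_5 alone (medians -0.51, -0.41 and -0.55, adjusted p = 0.063, 0.085 and 0.146). Cholesterol synthesis genes had a median of -0.15 (adjusted p = 0.0025, and adjusted p = 0.468 with an estimated correlation), and of -0.08 without Hyp_4 and -0.10 without cFGF23-Hyp_2. Among them, Insig1 had a log2 change of -0.68 (adjusted p = 0.216). The FGF receptor and ERK feedback list had a median of -0.20 (adjusted p = 0.0036, and adjusted p = 0.499 with an estimated correlation). Etv4 was at 2.77 ± 0.752 CPM in Hyp and 0.999 ± 0.323 in cFGF23-Hyp (SD, n = 5 each; log2 change -1.45 ± 0.28 SE, adjusted p = 0.163). Lcn2, Cx3cl1 and Tnfaip2 had log2 changes of -0.83, -0.39 and -0.47 (adjusted p = 0.285, 0.232 and 0.310). Macrophage markers, with a median of -0.19, did not pass camera (adjusted p = 0.131).

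Oxidative phosphorylation, ribosomal protein and heat shock genes had medians of 0.23, 0.16 and 0.22, with camera adjusted p of 1.6e-07, 1.0e-04 and 0.020, and an adjusted p = 0.632 with an estimated correlation for each. The first pair went with cFGF23-Hyp_3, whose scores were 0.71 and 0.69, against -0.23 to 0.23 and -0.19 to 0.19 in the other 14 libraries. Without cFGF23-Hyp_3 alone these 2 lists had no call (medians 0.00 and -0.02, adjusted p = 0.948 for the former and also above 0.05 for the latter). The heat shock score was 0.29 in cFGF23-Hyp_3 and 0.55 in cFGF23-Hyp_5, and that list lost its call without WT_5 and cFGF23-Hyp_5 (median 0.06, adjusted p = 0.348). It also lost it without Hyp_2, Hyp_4, Hyp_5, cFGF23-Hyp_3 or cFGF23-Hyp_5 alone (medians 0.21, 0.22, 0.21, 0.15 and 0.06, adjusted p = 0.097, 0.071, 0.058, 0.107 and 0.340), and its median was 0.44 without Hyp_3. Without cFGF23-Hyp_3, WT_5 and cFGF23-Hyp_5, the 3 medians were -0.04, -0.02 and -0.07. In the phosphate and vitamin D list 2 genes rose and 1 fell when adjusted over the list alone (median 0.02, camera adjusted p = 0.328). The log2 change was 0.30 ± 0.08 for Slc34a1 (adjusted p = 0.236), 0.35 ± 0.10 for Kl (adjusted p = 0.273) and -0.87 ± 0.21 for Slc34a2 (adjusted p = 0.210). It was -0.90 ± 0.58 for Cyp24a1 (adjusted p = 0.569) and, for Cyp27b1, 0.20 ± 0.43 (adjusted p = 0.878).

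No single gene passed edgeR's quasi-likelihood test in this comparison (0 calls, smallest adjusted p = 0.140), although 1647 genes had an unadjusted p below 0.05. DESeq2 called 116 (74 higher) and limma-voom 2. Leaving out cFGF23-Hyp_5 alone gave 25 calls, leaving out WT_5 or Hyp_2 gave 1 each, and without both WT_5 and cFGF23-Hyp_5 there were 67 (60 higher, 7 lower). The authors' deposited table lists 94 genes (61 higher, 33 lower), of which 44 are among the 67. Camera called 14 of 39 lists, 5 higher and 9 lower, and fry 0.

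**Figure D2:**
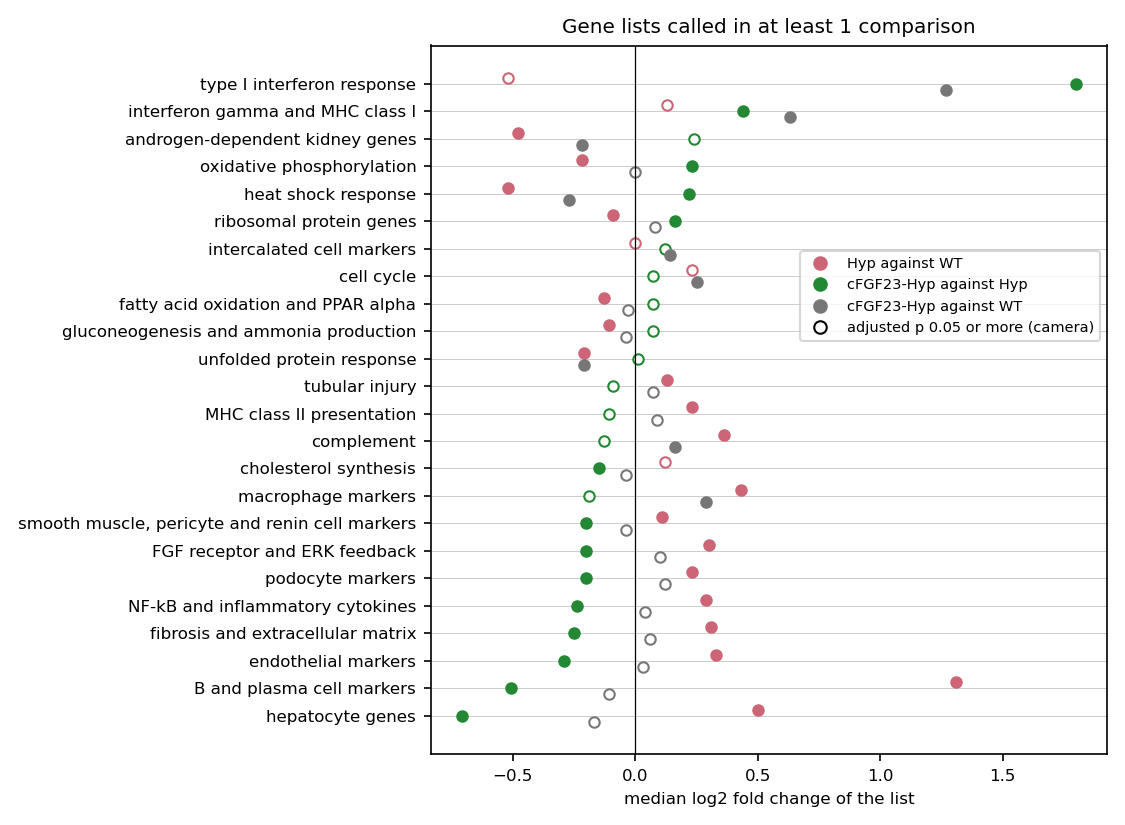
Median log2 fold change (horizontal axis) of the 24 gene lists called by camera with the preset correlation in at least 1 of the 3 comparisons, as points coloured by comparison, open where the adjusted p was 0.05 or more. Medians of type I interferon genes were 1.80 in cFGF23-Hyp against Hyp and 1.27 against WT, and those of B and plasma cell genes 1.31 in Hyp against WT and -0.51 in cFGF23-Hyp against Hyp.

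Both comparisons use the same Hyp libraries, which by itself gives opposite signs. Of the 54 genes called in Hyp against WT, 54 had the opposite sign in cFGF23-Hyp against Hyp (100%, exact 95% interval 93.4% to 100%). That interval treats genes as independent, though all come from the same 15 mice, so it measures no spread over mice. Without WT_5 and cFGF23-Hyp_5 the share was 88.2% of 228 called genes. Simulated unchanged groups, with all 15 libraries drawn anew and the simulated Hyp libraries shared, gave 94.2% on average (88.9% to 98.1%). That share was taken over the 54 genes with the smallest p in each simulation, whether called or not. Over all genes, the covariance of the log2 changes was -0.070, against -0.028 in the simulations (-0.029 to -0.026). Each gene was drawn on its own there, so that range leaves out correlation between genes and cannot show how unusual -0.070 is. With the Hyp libraries split 3 and 2, so that the comparisons shared none, the covariance was -0.043 on average (-0.051 to -0.035 over the 10 splits). The covariance with none shared was -0.029 without WT_5 and cFGF23-Hyp_5 (-0.039 to -0.017). For Etv4 the group means were 0.914, 2.77 and 0.999 CPM in WT, Hyp and cFGF23-Hyp, and for Ces1g 3.11, 121 and 15.2 CPM. These genes are examples, and how many lay as near WT was not counted. Nat8f2, also called in Hyp against WT, lay at 63.8 to 71.9 CPM in cFGF23-Hyp_1 to cFGF23-Hyp_4, against 27.7 to 34.5 CPM in WT_1 to WT_4. It was at 53.9 CPM in WT_5 and 33.5 CPM in cFGF23-Hyp_5. The group means of Etv4 and Ces1g include these last 2 libraries.

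The comparison of cFGF23-Hyp with WT asks what still differs from WT after the treatment. The type I interferon list had a median of 1.27, with 33 of 33 genes positive and 28 risen when adjusted over the list alone (camera adjusted p = 1.5e-38, adjusted p = 0.246 with an estimated correlation). Ifit1 was at 3.01 ± 3.18 CPM in WT and 14.2 ± 10.7 in cFGF23-Hyp (SD, n = 5 each; adjusted p = 0.668), where the WT mean includes 8.67 CPM in WT_5 and 1.29 to 2.09 in WT_1 to WT_4. Interferon gamma and MHC class I genes had a median of 0.63, with 9 of 24 risen when adjusted over the list alone (adjusted p = 4.5e-19, and adjusted p = 0.246 with an estimated correlation). Bst2 and B2m had log2 changes of 1.73 and 0.63, each with an adjusted p of 0.668. Macrophage markers (median 0.29) and complement genes (0.16) passed camera with adjusted p of 2.3e-04 and 0.037, and had adjusted p of 0.768 and 0.787 with an estimated correlation. C2, an early complement component, had a log2 change of 0.71 ± 0.19 (adjusted p = 0.668). The type I interferon median was 1.96 without WT_5, and 2.21 without WT_5 and cFGF23-Hyp_5, which were set apart partly by that score. The complement median was 0.27 without cFGF23-Hyp_5 and 0.32 without both. Its call was lost without WT_1, WT_2 or any 1 of cFGF23-Hyp_1 to cFGF23-Hyp_4 (medians 0.08 to 0.20, adjusted p = 0.067 or more), and the macrophage median was 0.19 without cFGF23-Hyp_3.

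Cell cycle genes had a median of 0.25 (adjusted p = 0.0059, and adjusted p = 0.787 with an estimated correlation) and intercalated cell markers 0.14 (adjusted p = 0.010, and adjusted p = 0.768 with an estimated correlation). Among lists of cFGF23-Hyp against WT that lay lower, unfolded protein response, heat shock and androgen-dependent genes had medians of -0.21, -0.27 and -0.22, with adjusted p of 2.3e-04, 2.3e-04 and 0.012, and an adjusted p = 0.768 with an estimated correlation for each. Without WT_5 and cFGF23-Hyp_5 the medians of intercalated cell, heat shock and androgen-dependent genes were 0.25, -0.48 and -0.36, and the cell cycle call was lost at a median of 0.26 (adjusted p = 0.085). The cell cycle call was also lost without WT_4 (0.20, adjusted p = 0.138) or cFGF23-Hyp_2 (0.04, adjusted p = 0.634). That of intercalated cell markers was lost without WT_2, cFGF23-Hyp_2 or cFGF23-Hyp_4 (0.10, 0.10 and 0.11, adjusted p = 0.166, 0.112 and 0.092). The androgen-dependent call was lost without WT_1, WT_2 or cFGF23-Hyp_4 (-0.15, -0.15 and -0.08, adjusted p = 0.062, 0.159 and 0.265). Without WT_4 the unfolded protein response and heat shock calls were lost (-0.13 and -0.16, adjusted p = 0.135 and 0.068). The heat shock median was -0.42, -0.06, -0.16 and -0.43 without WT_1, WT_3, cFGF23-Hyp_1 and cFGF23-Hyp_5. Medians of the matrix, endothelial and NF-kB lists were 0.06, 0.03 and 0.04 and did not pass camera (adjusted p = 0.534, 0.833 and 0.287). These last 3 medians also depend on WT_5 and cFGF23-Hyp_5, the latter with an endothelial score of -0.57 and a matrix score of -0.47. Without both they were 0.14, 0.12 and 0.16 (adjusted p = 0.015, 0.053 and 0.018), with an adjusted p = 0.677 for matrix and 0.663 for NF-kB genes with an estimated correlation. Without both, hepatocyte and mitochondrially encoded genes also gained a call (medians -0.14 from -0.17 and -0.09 from -0.01, adjusted p = 0.0014 and 0.046, but 0.140 and 0.677 with an estimated correlation). The hepatocyte call was upward, with 2 of 6 genes positive and a mean of 0.41.

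For single genes edgeR made 0 calls here (smallest adjusted p = 0.668, with 905 genes at an unadjusted p below 0.05), DESeq2 6 and limma-voom 0. Leaving out WT_5 gave 3 calls, and leaving out WT_5 and cFGF23-Hyp_5 gave 177 (134 higher, 43 lower). In that fit 30 of the 33 type I interferon genes and 9 of the 24 interferon gamma and MHC class I genes rose, and both lists were called with an estimated correlation (adjusted p = 0.0044 and 0.0071, against 0.246 for each with all libraries). As both libraries were set apart partly by their interferon score, these values are no independent evidence of a rise. B2m, the light chain of MHC class I, rose there by 0.90 ± 0.13 (adjusted p = 0.0024), Slc22a8 by 1.11 ± 0.18 (adjusted p = 0.0056) and C2 by 1.05 ± 0.11 (adjusted p = 3.2e-04). WT_5 also stood apart from WT_1 to WT_4 in Slc22a8, so the value of Slc22a8 rests partly on leaving WT_5 out. Slc34a1, Kl, Cyp24a1 and Cyp27b1 had log2 changes of -0.12, -0.24, 0.99 and 1.61 in that fit and did not pass the test (adjusted p = 0.783, 0.475, 0.701 and 0.105).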

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

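All tests of explanations in this part were chosen, or for the splits of the samples had their possible outcomes stated, only after the results were seen. In 222 groups of 5 values (scores of 39 lists, CPM of 31 genes, and the total count, the number of genes with a count, the share of the 10 highest genes and the mitochondrial share), 22 had a highest or lowest library far from the others, where chance gives about 1 in 20 groups, or 11. Of these, 5 fell on WT_5, 6 on cFGF23-Hyp_5 and 3 on cFGF23-Hyp_3.

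In WT, the library labelled WT_5 stood above the others in the type I interferon score (1.12, others -0.90 to -0.57), Ces1g (9.59 CPM, others 1.07 to 2.01), Fgf10 (4.39 CPM, others 2.04 to 2.48), Nat8f2 (53.9 CPM, others 27.7 to 34.5) and Slc22a8 (378 CPM, others 213 to 249). In cFGF23-Hyp, the library labelled cFGF23-Hyp_5 stood below the others in the scores of complement (-0.48), principal cell (-0.37), endothelial (-0.57) and hepatocyte genes (-1.25) and in Nat8f2 (33.5 CPM, others 63.8 to 71.9). It stood above them in Ctnna2 (7.34 CPM, others 3.04 to 4.05).

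Both libraries lie apart from the groups their titles give. On an axis over 500 genes from WT (0) to cFGF23-Hyp (1), WT_5 lay at 0.79 and cFGF23-Hyp_5 at 0.08. WT_1 to WT_4 lay at 0.09 to 0.26 and cFGF23-Hyp_1 to cFGF23-Hyp_4 at 0.62 to 0.95. Each axis was drawn without the library placed on it. WT_5 and cFGF23-Hyp_5 were left out of every axis, a choice made after they had stood apart. That WT_5 was an untreated Hyp mouse, as its genotype and cell type labels could be read, is argued against by its position of 0.75 from Hyp (0) to cFGF23-Hyp (1), where the Hyp libraries lay at 0.09 to 0.19. From WT (0) to Hyp (1), cFGF23-Hyp_5 lay at 0.10 and WT_5 at 0.62. WT_1 to WT_4 lay at 0.02 to 0.22 there, cFGF23-Hyp_1 to cFGF23-Hyp_4 at 0.47 to 0.86 and the Hyp libraries at 0.85 to 1.06. On this axis each of the 2 libraries was thus in the range of the other's group. An exchange of their labels remains a candidate explanation, with both partners out of place, while a biological difference of these mice was not tested. No library was moved between these groups.

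The type I interferon genes stood higher in cFGF23-Hyp than in Hyp. More immune cells in the treated kidneys would raise immune cell markers too, yet the highest median log2 change of 4 immune cell lists was -0.09, and the lower quartile of the interferon genes was 1.03. That highest median was of T and NK cell markers, with 6 tested genes and an upper quartile of 0.12. The medians of the 4 lists include cFGF23-Hyp_5, with a macrophage score of -0.47, against 0.03 to 0.39 in the other treated libraries. Without it and WT_5, macrophage, T and NK, and B and plasma cell scores differed from Hyp by -0.03, -0.08 and -0.93. Compared with WT, and without the same 2 libraries, macrophage scores were higher both in cFGF23-Hyp (by 0.44) and in Hyp (by 0.47). The neutrophil list had fewer than 5 tested genes. Whether the vector itself, rather than cFGF23, may raise these genes stays open and the 2 cannot be told apart, because 0 libraries came from mice given a vector without cFGF23. An effect of cFGF23 is the biological hypothesis left open beside it.

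The log2 changes of Hyp against WT and of cFGF23-Hyp against Hyp ran in opposite directions. The shared Hyp libraries alone would in expectation leave no covariance once none are shared. With the Hyp libraries split it was -0.043 on average (-0.051 to -0.035), and -0.029 without WT_5 and cFGF23-Hyp_5 (-0.039 to -0.017). All splits reuse the same mice, and the spread of this value in unchanged groups with correlated genes was not computed. The splits therefore cannot decide whether a covariance of this size could arise in unchanged groups. A trend with gene length (Spearman's rho across genes 0.21 and -0.21, genes not being independent) is argued against as the whole cause, since the covariance after its removal was -0.068, against -0.070 before. Handling of the Hyp libraries apart from the other 10 could give the same pattern and stays open, as the labels give no batch. A partial return of gene expression towards WT under treatment is a hypothesis that these data leave open as well.

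Of 100 splits of the 10 libraries of Hyp and WT, 1, the real one, gave 54 or more genes, and the highest other gave 2. Chance is thus an unlikely explanation of that count, though 1 in 100 is the smallest share these splits can give. For the 19 lists called in Hyp against WT 21 splits gave as many (highest other 23), and chance cannot be excluded. For the 14 lists called in cFGF23-Hyp against Hyp 43 splits gave as many (highest other 22), and for the 9 in cFGF23-Hyp against WT 82 (highest other 23), so chance is not excluded for these either. In both comparisons edgeR called 0 genes (1647 and 905 at an unadjusted p below 0.05, 116 and 6 called by DESeq2, 2 and 0 by limma-voom), a count that any split reaches (100 of 100, highest other 1 and 208), so the splits say nothing on chance there. For cFGF23-Hyp against WT the highest other split called 208 genes and set WT_1 to WT_4 and cFGF23-Hyp_3 against the rest, which points to a structure of the samples. The split that exchanges WT_5 and cFGF23-Hyp_5 was not among the 100 refitted, so its count is not known.

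In cFGF23-Hyp_3 the scores of oxidative phosphorylation (0.71, others -0.20 to -0.06), ribosomal protein (0.69, others -0.19 to 0.00) and renin-angiotensin genes (-0.21, others 0.06 to 0.08) lay apart from the other 4 treated libraries. The androgen-dependent score was -0.71 in cFGF23-Hyp_4, against -0.03 to 0.23 in the others. In Hyp, the scores of calcium reabsorption in Hyp_3 (-0.09), amino acid and organic anion transport in Hyp_4 (-0.07) and type I interferon genes in Hyp_2 (-0.85) lay below the others. Dnase1 was at 464 CPM in Hyp_1 (others 611 to 619) and Fat2 at 2.43 CPM in Hyp_2 (others 1.84 to 1.98). In WT_1, Ctnna2 was at 8.12 CPM (others 5.05 to 5.70) and Slc34a1 at 4969 CPM (others 4508 to 4580).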

How the results depend on the processing

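The fits without WT_5 and cFGF23-Hyp_5, those that also left out cFGF23-Hyp_3 and the removal of the length trend were chosen after the data were seen, and the other alternatives before. Over all alternatives run, 357 results for named genes kept direction and side of the threshold 8441 times, lost a call 169 times, gained one 279 times and turned direction 24 times. The medians of 42 called lists did so 899 times, with 63 calls lost and 4 turns. None of the 54 genes called in Hyp against WT turned sign in the alternatives run on them. DESeq2's size factors kept 54 of them, DESeq2's test 53, limma-voom 52, no filter 43 and the stricter filter 48.

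Called genes in Hyp against WT (54 with edgeR) numbered 356 with DESeq2, 516 in a fit of these 2 groups alone (53 of the 54 kept), 97 with WT_5 placed in Hyp (24 kept), 228 without WT_5 and cFGF23-Hyp_5 and 1527 without these and cFGF23-Hyp_3. With each library left out in turn they ran from 7 (without Hyp_1) to 345 (without cFGF23-Hyp_3). In cFGF23-Hyp against Hyp (0 with edgeR, 1647 at an unadjusted p below 0.05) they were 116 with DESeq2, 2 with limma-voom, 67 without the pair and 63 without the 3 libraries, and 0 to 25 (without cFGF23-Hyp_5) with 1 library left out. In cFGF23-Hyp against WT (0 with edgeR, 905 unadjusted, 0 with limma-voom) they were 6 with DESeq2, 1 with WT_5 placed in Hyp, 177 and 583 without the 2 or 3 libraries, and 0 to 3 (without WT_5) with 1 left out. Why DESeq2 and edgeR differed was not tested.

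The replicate block left 15 genes in Hyp against WT, 14 of them among the 54. Of 15 same-numbered pairs, correlations of deviations ran from -0.31 to 0.29, and 7 of 15 libraries correlated best with their own number. The numbers were not taken as pairing because the labels do not say that they pair mice. These values do not exclude a structure by number, and the choice matters, since the block ended 40 of the 54 calls. In the other comparisons the block gave 0 calls by edgeR.

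Lists called by camera (19, 14 and 9) fell to 0, 0 and 0 with an estimated correlation, and fry called 3, 0 and 0. CameraPR on limma-voom called 20, 13 and 8, and after removal of the length trend 21, 19 and 8, among them 18, 14 and 8 of the lists called by camera. Without the 3 libraries cFGF23-Hyp against WT had 18. The share of called genes with opposite sign (100%) was 92.8% with WT_5 placed in Hyp, 88.2% and 76.0% without the 2 or 3 libraries, fits for which unchanged groups were not simulated. With the Hyp libraries split, so that none were shared, it was 81.8% on average without the 2 libraries (71.2% to 93.0%). As for opposite-direction genes, covariance over all genes tested (-0.070) was -0.489 with no filter, which adds genes of few counts, and -0.043 with the Hyp libraries split.

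Log2 changes that turned were the following, and the cause was not tested. Without WT_5 and cFGF23-Hyp_5, the uncalled type I interferon median in Hyp against WT was 0.14 (from -0.52). With WT_5 placed in Hyp, in Hyp against WT, Egr1 was 0.64 (from -0.69), Hba-a1 -0.20 (from 0.21), Oas1a 0.95 (from -1.48) and Oas2 0.90 (from -1.56). With the stricter filter, Icos in cFGF23-Hyp against WT was -0.02. Without the 3 libraries, in cFGF23-Hyp against Hyp, Col1a1 was 0.12, Fgfr1 0.03, Hspa1a -0.43 (-0.18 without the pair) and Hspe1 -0.10, and the medians of oxidative phosphorylation, heat shock and ribosomal protein genes -0.04, -0.07 and -0.02. In cFGF23-Hyp against WT, Egf was 0.06, Fgfr1 0.12, H2-Eb1 0.00, Rpl3 -0.04 and Rpl7 -0.04. With 1 library left out, Havcr1 in Hyp against WT ran from -0.18 to 0.26. In cFGF23-Hyp against Hyp, Hspa1a ran from -0.19 to 1.91, Ren1 from -0.24 to 0.05 and the ribosomal list median from -0.02 to 0.23. In cFGF23-Hyp against WT the ranges were -0.07 to 1.22 for Cfd, -0.09 to 0.29 for Col1a1, -0.07 to 0.27 for H2-Eb1, -0.03 to 1.83 for Retn, -0.02 to 0.28 for Rpl3 and 0.00 to 0.34 for Rpl7. Depth limits genes of few counts, of which Tnf, Il6 and Ccl2 could not be tested.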

Other observations

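The permutation tests of list scores and the length trend were chosen after the data were seen. Along the distal nephron, single genes of Hyp against WT went both ways. Calb1, a calcium-binding protein of the distal tubule, had a log2 change of -0.69 ± 0.16 (adjusted p = 0.081, edgeR), and Slc12a3, the thiazide-sensitive sodium chloride transporter, 0.39 ± 0.10 (adjusted p = 0.093). Among 16 distal convoluted and connecting tubule markers, 1 rose and 2 fell when adjusted over the list alone, 0 over all genes tested, with a median of -0.01 (camera adjusted p = 0.864). Without WT_5 and cFGF23-Hyp_5, Calb1 fell (-0.79, adjusted p = 0.025). Slc22a12, the urate transporter of the proximal tubule, had a log2 change of -0.54 ± 0.11 (adjusted p = 0.051) and fell without the 2 libraries (-0.63, adjusted p = 0.0077). Medians of thick ascending limb (0.07), principal cell (0.06), calcium reabsorption (0.04) and amino acid and organic anion transport genes (-0.02) did not pass camera (adjusted p = 0.268, 0.155, 0.891 and 0.891).

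Clock genes had a median of -0.16 in Hyp against WT (camera adjusted p = 0.052, and 0.0092 with cameraPR after removal of the length trend, but 0.409 with an estimated correlation and the trend left in), with 2 of 19 fallen when adjusted over the list alone and 0 over all genes. Usp2 had a log2 change of -0.69 ± 0.18 (adjusted p = 0.119). In cFGF23-Hyp against WT, Arntl, a core clock transcription factor gene, had a log2 change of -0.60 ± 0.17 (adjusted p = 0.668), and fell without WT_5 and cFGF23-Hyp_5 (-0.80, adjusted p = 0.036). The glutathione transferase gene Gsta2 had a log2 change of 1.46 ± 0.35 in Hyp against WT (adjusted p = 0.082), while the NRF2 and oxidative stress list had a median of -0.11 (camera adjusted p = 0.837). Medians of adipocyte (0.24), red blood cell (0.14), urothelial (-0.31), renin-angiotensin (0.09), cholesterol synthesis (0.12) and mitochondrially encoded genes (-0.15) did not pass camera in that comparison with all libraries (adjusted p = 0.837, 0.496, 0.837, 0.542, 0.097 and 0.056). The last of these lists passed without WT_5 and cFGF23-Hyp_5 (median -0.18, adjusted p = 0.045, and adjusted p = 0.496 with an estimated correlation).

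Scores of 39 lists were also compared between groups by exact two-sided permutation tests, and none passed adjustment over the lists. In Hyp against WT, podocyte, hepatocyte and B and plasma cell scores were higher in 5 of 5 Hyp libraries than in any WT library (exact p = 0.0079 each, the smallest that 5 against 5 can give, adjusted p = 0.103). Macrophage and matrix scores were above every WT library in 4 of 5 Hyp libraries (exact p = 0.016 each, adjusted p = 0.103). Oxidative phosphorylation scores were below every WT library in 4 of 5 Hyp libraries (exact p = 0.016, adjusted p = 0.103). In cFGF23-Hyp against Hyp, scores of NF-kB, B and plasma cell, podocyte and hepatocyte genes were below every Hyp library in 4 of 5 treated libraries (exact p = 0.016 each, adjusted p = 0.155).

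On chromosome X, which carries Phex, lay 2 of the 54 genes called in Hyp against WT (3.70%), against 3.07% of the genes tested (Fisher's exact test, two-sided p = 0.682). Ttr was at 463 CPM in the library labelled WT_5 and at 44.3 to 79.4 CPM in WT_1 to WT_4, and at 55.5 CPM in the library labelled cFGF23-Hyp_5.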
